A study of Homo sapiens with 5 samples.

How the data were processed

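The data were 5 droplet libraries of 5' single-cell RNA from 4 biopsy sources of Hodgkin lymphoma. The deposited files held counts of UMIs per gene and barcode for each library, not normalized, with the genes and barcodes in separate lists. Per the submitters' processing notes, Cell Ranger 2.1.1 and the genome build GRCh38 were used. How the authors separated cells from empty droplets was not given in the sources used here, and no cell type annotation was used here. The deposited matrices listed 33538 genes, and the lowest UMI total of a barcode was 500. Of the gene identifiers 33456 were found in GENCODE 29, which gave the coordinates on GRCh38.

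The 5 libraries fall in 1 group, so no groups of samples were compared. Replicates were the source numbers of the labels, with Run1 and Run2 of source 6 summed. The runs shared 76 barcodes, of 6311 in the smaller run, and were read as separate libraries. The rate over all library pairs except sources 1 and 2 gives 77.1, but that rate includes the pair of runs itself. Comparisons were made between cell classes within sources, and the tests, gene lists, markers, rule for named genes and most alternatives were fixed before the data were examined. Genes that depend on a donor's genotype or sex, 114 in number, were left out of all tests and tables.

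Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs, which left 22950 of 24824. Of the barcodes 287 had too few genes and 1707 too much mitochondrial RNA. Doublets were called with scrublet per library. Its automatic threshold marked under 0.5% of Run2, so there the cells with the highest scores were removed at 0.8% per 1000 cells, and 788 cells were removed in all, 558 of them from Run2. Counts were log-normalized to 10000 per cell. The 2000 most variable genes by source were scaled within each source, with the gene lists, receptor segment, ribosomal, mitochondrial and person-dependent genes left out. Then 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0 gave 30 clusters. Clusters were named from 22 marker lists. A cluster stayed unnamed where cell cycle genes led it, where fewer than 3 markers of each list passed 2-fold, where NK and T cell markers stood together, where another list held more of its leading genes, or where its depth was low against its library with no marker among its leading genes. Tools were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

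For each comparison the counts were summed per source and class, and a source entered with at least 20 cells in both classes. All 4 sources entered each of the 4 comparisons. The sums were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) after filterByExpr and TMM scaling, with the source as a block and Benjamini-Hochberg adjustment at 0.05. The 2000 clustering genes and all markers were left out of the tests, since they define the classes, which left 31372 testable genes. The numbers pair the sums because both come from the same biopsy. As a check, deviations of same-numbered sums from the class means correlated in all 16 pairs, from 0.113 to 0.523. The robust setting of the dispersion estimate was the first to be run on the data, and the default took its place after tests on simulated data, so the robust setting is among the alternatives. CPM are means of the sources with their SD and were computed on sums over all cells of a class. The SE of a log2 difference was derived from the test, as its absolute size over the square root of the F statistic. It draws on dispersion shared across genes and can be narrower than the spread of the sources' own ratios. A class can draw on different clusters in different sources, and free RNA adds low counts of abundant genes to all classes.

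Gene lists, 16 in number, were tested where at least 5 members could be tested, with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Named genes followed a rule. From each list up to 3 genes with the largest absolute log2 fold change among those that passed were taken, then up to 5 higher and 5 lower genes over all tested genes with the same sign in each source and at least 50 CPM in the higher class mean. Receptor segment, ribosomal, mitochondrial and unnamed clone genes were left out of the second part, and 12 checkpoint and chemokine genes could be named in any class. Other list members named in the text were chosen after their values were seen, as were the genes named for the runs among those that met the size rule. Genes with near-identical copies, such as HLA genes, KLRC1, HSPA1A, CCL4 and IFITM1, are uncertain, since the handling of reads that match several copies was not given in the sources used here. A class at 0 counts was set to a floor of 3 counts over the group, and 1 to 3 counts were given as a ratio with an exact interval. Intervals are at 95% and cover counting error only.

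The test was checked on simulated data with the sources' means, depths and spread and 200 changed genes. At 2-fold it recovered 64.6% of changed genes for CD8 T-like against CD4 T-like (10347 genes), 52.6% for Treg-like (8523 genes), 57% for B-like (11193 genes) and 36.1% for myeloid-like cells (10468 genes). At 4-fold it recovered 96%, 96%, 92.9% and 84.4%. Of the calls 7.5%, 9.3%, 9.7% and 11.5% were unchanged genes, above the nominal 5%, so a share of the called genes is likely false. Only 200 genes were changed, fewer than passed in each real comparison, so the size of that share does not carry over. Genes with low mean counts were not among the changed ones, so recovery of such genes was not measured. The median log2 difference of all fitted genes, clustering genes and markers included, lay between -0.10 and -0.01. DESeq2's size factors did not move it by more than 0.1 in any comparison. Without scaling factors it was -0.11, 0.10, -0.13 and -0.21.

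Alternatives were DESeq2, its size factors (RLE), no low-count filter, no replicate block, glmTreat with a log2 fold of 1, each source left out, either run of source 6 alone, no doublet removal (28 clusters), Leiden resolution 0.6 (22 clusters), at most 10% mitochondrial UMIs, at least 500 genes, cells thinned to 1000 UMIs and at least 50 cells per class and source. Robust dispersion estimates, only the GZMK-led CD8 cluster, no FOXB1-led cluster and no PLA2G2D-led cluster were added after seeing the data. Levels of a few genes in the runs were compared by size alone, since each run is 1 library.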

Results

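Single-cell 5' gene expression was measured in needle-core tumour biopsies of Hodgkin lymphoma, a lymph node disease in which rare malignant Hodgkin Reed-Sternberg cells lie in a large infiltrate of lymphocytes and myeloid cells. The labels name 4 biopsy sources, numbered 1, 2, 3 and 6, and give source 6 as Run1 and Run2, which makes 5 droplet libraries in 1 group. The files held 24824 barcodes and 98350330 unique molecular identifiers (UMIs, each a counted RNA molecule). Source 1 had 5769 barcodes and 25304413 UMIs, source 2 had 2733 and 11449786, and source 3 had 1427 and 4023231. Run1 of source 6 had 6311 barcodes and 13405146 UMIs, and Run2 had 8584 and 44167754. Median UMIs per barcode ranged from 1739 in Run1 to 4536.5 in Run2. After filters on genes, mitochondrial RNA and doublets, 22162 cells remained, 4776, 2314 and 1202 from sources 1, 2 and 3 and 6080 and 7790 from the runs. The sources are the replicates of all tests and enter as a block. The p-values thus rest on how the class difference within a source varies over these 4 sources, with dispersion shared across genes. The labels leave open what a run of source 6 was, and its cells were summed over both runs unless a run is named.

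T-like cells were the largest class and CD4 T-like cells the largest part of them. All T-like cells made up 59.0% ± 16.5 of kept cells (SD, n = 4 sources), with a range from 39.0% in source 2 to 79.0% in source 3. CD4 T-like cells, helper cells named from markers such as CD40LG and IL7R, held 37.7% ± 4.28. Treg-like cells, named from FOXP3, the master regulator of regulatory T cells, and IL2RA, held 2.68% ± 1.40. CD8 T-like cells, the killer lineage, held 14.9% ± 10.7 and ranged from 4.19% to 29.5%. B-like cells held 23.0% ± 12.0 and ranged from 7.49% in source 3 to 33.5% in source 2. Monocyte/macrophage-like and dendritic-like cells, summed as myeloid-like, held 5.71% ± 2.90. NK-like cells held 2.70% ± 2.00, antibody-secreting plasma-like cells 2.13% ± 2.60 and plasmacytoid dendritic-like cells 0.565% ± 0.471. A T-like cluster whose markers mixed the CD4 and CD8 lineages held 3.69% ± 4.75, from 0.346% in source 2 to 10.6% in source 3, and unnamed clusters 6.27% ± 3.16. Endothelial-like cells held 0.359% ± 0.717, fibroblast-like cells 0.162% ± 0.213 and erythroid-like cells 0.036% ± 0.0721, with 0 endothelial-like and 0 erythroid-like cells in sources 1, 2 and 3, and 4, 2, 0 and 66 fibroblast-like cells in sources 1, 2, 3 and 6. A count of 0 among the 4776 cells of source 1 allowed a share of up to 0.0628%. Without source 2 the plasma-like mean was 0.858% and the plasmacytoid mean 0.35%, and without source 3 the NK-like mean was 1.74%. With coarser clusters the Treg-like mean was 5.62%, but FOXP3 was then seen in 39.0% of the Treg-like cells, against 70.2% here. With 1 group there was no contrast to test, and shares were not corrected for cells lost during tissue handling.

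**Figure D1:**
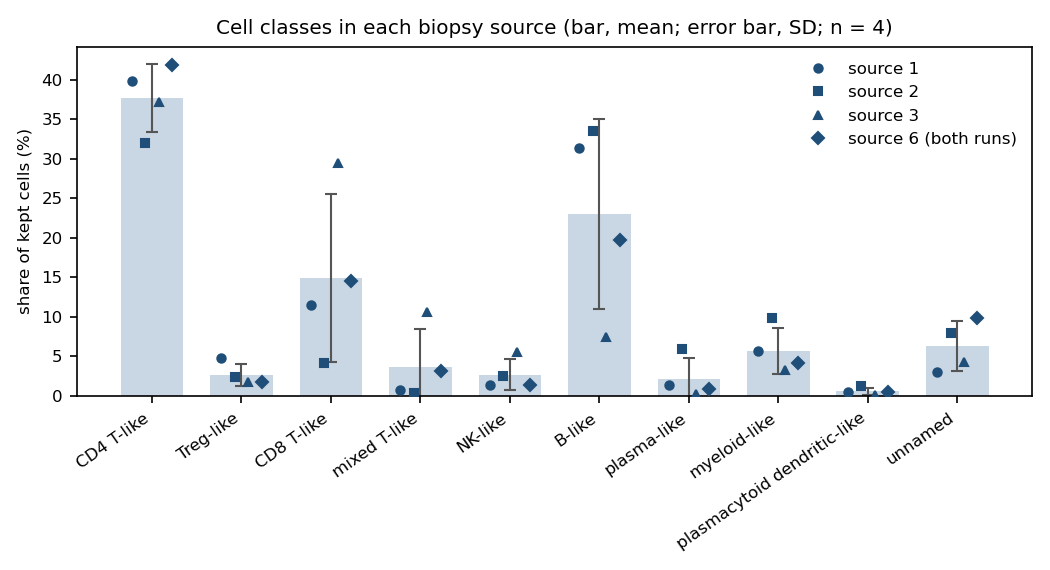
Share of kept cells (y axis, %) in each cell class (x axis) for the 4 biopsy sources (points), with the mean as a bar and the SD as an error bar. CD4 T-like cells lie between 32.0% and 41.9% in the 4 sources, while B-like cells span 7.49% to 33.5%.

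CD8 T-like cells carried the RNA of the killing machinery, of IFNG and of CCL4 at many times the level of CD4 T-like cells. CTSW, a cathepsin of cytotoxic lymphocytes, stood at 430 ± 171 CPM (counts scaled to equal totals; SD, n = 4 sources) in CD8 T-like against 20.5 ± 18.9 in CD4 T-like cells, Treg-like cells included. PRF1, which encodes the pore-forming perforin, stood at 234 ± 122 against 26.3 ± 6.37 CPM, and IFNG, the cytokine interferon gamma, at 77.0 ± 55.9 against 5.87 ± 3.58 CPM. CCL4, an inflammatory chemokine, had 811 ± 365 against 23.8 ± 22.7 CPM. In the other direction CTLA4, an inhibitory receptor that competes for CD28 ligands, had 35.1 ± 19.5 CPM in CD8 T-like and 278 ± 157 CPM in CD4 T-like cells, and IL21, the helper cytokine that acts on B cells, had 2.21 ± 3.13 against 48.4 ± 32.7 CPM.

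By gene list, 9 of 12 tested cytotoxic effector genes were higher in CD8 T-like cells and 0 were lower, among them the killer-cell lectin receptors KLRC1 (log2 difference 5.85, SE 0.61) and KLRK1 (5.80, SE 0.52), the surface receptor SLAMF7 (5.12, SE 0.55) and EOMES, a transcription factor of effector and memory killer cells (4.13, SE 0.64). Adjusted over the list alone, 11 were higher. Among 15 checkpoint receptors, which restrain or mark activated T cells, 5 were higher and 2 lower, or 7 and 3 adjusted over the list alone. CD160 (5.48, SE 0.43), CD244 (3.73, SE 0.32) and KLRG1 (2.90, SE 0.32) were higher, and BTLA (-1.77, SE 0.34) and CTLA4 (-2.89, SE 0.12) lower. PDCD1, the gene of PD-1, did not pass, with 61.6 against 57.2 CPM, a log2 difference of -0.03 (SE 0.27) and an adjusted p of 0.9995 by edgeR's quasi-likelihood test. LAG3 did not pass either, at 199 against 92.0 CPM. Of 11 MHC class II presentation genes 5 were higher and 0 lower, or 7 and 0 adjusted over the list alone, with HLA-DOA (2.25, SE 0.38) and HLA-DPB1 (1.28, SE 0.16) as examples. Of 14 MHC class I presentation genes 1 was higher, the immunoproteasome subunit PSMB9 (0.56, SE 0.12), or 9 adjusted over the list alone. Of 16 JAK-STAT targets 4 were lower and 0 higher, or 6 and 2 adjusted over the list alone, among them the kinase PIM2 (-1.21, SE 0.20) and SOCS3, a feedback inhibitor of cytokine receptors (-0.90, SE 0.15). Chemokine receptors split, with 3 of 11 higher and 1 lower, or 6 and 2 adjusted over the list alone. CX3CR1, the fractalkine receptor of cytotoxic cells, was higher (5.31, SE 0.65), and CCR6, a receptor of helper and B cells, was lower (-1.74, SE 0.25). An FGFBP2-led cluster of 307 cells with CX3CR1 among its leading genes stayed unnamed, since NK and T cell markers stood together. CD3E was seen in 80.5% and CD8A in 37.8% of its cells, and the CD8 T-like shares and levels leave them out. Of 17 cytokines 1 was higher and 2 were lower, or 4 and 4 adjusted over the list alone, IFNG against IL21 and AREG (-1.34, SE 0.30), a growth factor of tissue repair. Checkpoint ligands and suppressive factors had 2 of 8 higher and 1 lower, the costimulatory ligand TNFSF9 (4.20, SE 0.41) being higher and LGALS9, a galectin, lower (-0.95, SE 0.18), with the same counts adjusted over the list alone. CCL4 was the only one of 7 chemokines that passed, with 2 higher and 1 lower adjusted over the list alone. B cell receptor signalling had 2 of 7 higher, in both counts, the adaptor PIK3AP1 (3.53, SE 0.52) and the phospholipase PLCG2. The lysosomal list had 1 of 14 lower in both counts, CTSB (-1.40, SE 0.15), a cathepsin, and dissociation stress genes 1 of 17 higher, the heat-shock cochaperone DNAJB1 (0.76, SE 0.17), or 4 adjusted over the list alone. Of 27 interferon response genes 0 passed, or 6 higher and 2 lower adjusted over the list alone. Cell cycle (20 genes), NF-kB targets (19 genes) and quiescence and egress genes (11 genes) had 0 passing in both counts. A cluster of 393 cells led by cell cycle genes, with CD3D in 65.6% of them, was left out of all classes in each comparison, so the cell cycle counts and list tests do not measure how much the classes divide. Beyond the lists, CD4 T-like cells were higher in the interleukin receptor IL6R (105 ± 37.9 against 15.6 ± 5.93 CPM), the extracellular matrix gene FBLN7, ASB2 and MAGEH1.

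By CPM without a floor, each named gene that passed had its direction in 4 of 4 sources, except IL21, AREG and PLCG2, in 3. In edgeR's quasi-likelihood test on class sums with the source as a block and Benjamini-Hochberg adjustment, 161 of 10586 genes were higher in CD8 T-like and 218 in CD4 T-like cells. Adjusted p was 0.00184 for CTSW, 0.00327 for PRF1, 2.73e-05 for CTLA4 and 0.00137 for IL21. Of these 379 genes 31 were receptor segment genes, whose reads can fall between near-identical copies. Camera with a preset correlation called 4 of 16 lists, cytotoxic effectors up (adjusted p = 4.05e-13), MHC class II up (9.69e-07), MHC class I up (4.28e-05) and cell cycle down (0.0166). With an estimated correlation the same lists had adjusted p = 0.555, 0.555, 0.555 and 0.689 in camera, so 0 lists passed, and fry also called 0. In limma's camera with the estimated correlation, 1 list, cytotoxic effectors, had an unadjusted p under 0.05 (0.0378). In the lysosomal list the median (0.03) was positive while the mean (-0.34) and the test were negative. The count of genes was 964 without source 1, 79 without source 2, 115 without source 3, 154 without source 6 and 36 without the block, and DESeq2 called 265 genes higher and 232 lower. Different clusters held most CD8 T-like cells, a CD248-led cluster 342 of 548 cells in source 1 and a GZMK-led cluster 314 of 355 in source 3, and with only the GZMK-led cluster 918 genes passed.

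Treg-like cells set against the other CD4 T-like cells were higher in 5 checkpoint receptors and 4 chemokine receptors. TIGIT, an inhibitory receptor for nectins, stood at 322 ± 127 CPM (SD, n = 4 sources) against 60.5 ± 21.5, and CTLA4 at 576 ± 280 against 257 ± 161. LAYN, a hyaluronan receptor of tumour Treg cells, had 30.6 ± 11.5 against 1.57 ± 1.13 CPM, and CCR8, a chemokine receptor of tissue Treg cells, 24.5 ± 12.1 against 4.04 ± 6.00 CPM. The other CD4 T-like cells were higher in TNFSF8, the ligand of the CD30 receptor, at 129 ± 42.5 against 33.1 ± 14.2 CPM. IL21 had 2 counts over all Treg-like cells and 1608 over the other CD4 T-like cells, 47.6 times less in Treg-like cells (95% counting interval 13.2 to 393).

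Of 13 checkpoint receptors 5 were higher in Treg-like cells and 0 lower, or 6 and 1 adjusted over the list alone, with LAYN (log2 difference 4.45, SE 0.47), the costimulatory receptor TNFRSF9 (4.24, SE 0.52), ENTPD1, an ectoenzyme that degrades extracellular ATP (3.10, SE 0.46), and TIGIT (2.19, SE 0.26). PDCD1 did not pass, at 27.3 against 58.7 CPM, nor did LAG3, at 150 against 86.9 CPM. Of 9 chemokine receptors 4 were higher and 0 lower, or 5 and 1 adjusted over the list alone, among them CXCR6 (2.12, SE 0.20) and CXCR3 (197 ± 52.7 against 76.7 ± 48.0 CPM), both receptors of T cells in inflamed tissue. Interferon response genes had 3 of 26 higher and 0 lower, or 7 and 1 adjusted over the list alone, namely OAS1 (1.44, SE 0.26), IFI6 (1.05, SE 0.18) and GBP5 (0.90, SE 0.21). MHC class II presentation had 2 of 8 higher, or 5 adjusted over the list alone, HLA-DMA (1.18, SE 0.26) and CD74 (0.58, SE 0.13), the invariant chain. JAK-STAT targets had 2 of 16 higher, or 4 adjusted over the list alone, the feedback inhibitor CISH (2.15, SE 0.34) and the survival gene BCL2L1 (1.26, SE 0.23). NF-kB targets had 1 of 18 higher, BIRC3 (0.86, SE 0.20), an inhibitor of apoptosis, or 3 higher and 1 lower adjusted over the list alone. Of 5 checkpoint ligands and suppressive factors 2 were higher in both counts, the galectins LGALS1 (2.15, SE 0.44) and LGALS3 (1.06, SE 0.25). Cytokines split, with lymphotoxin LTB higher and IL21, TNFSF8 (-1.79, SE 0.23) and AREG (-1.69, SE 0.26) lower among 15, or 5 higher and 5 lower adjusted over the list alone. Of 6 cytotoxic effectors PRF1 was higher (1.26, SE 0.26) and HOPX lower (-2.58, SE 0.54), or 1 and 2 adjusted over the list alone. Of 17 dissociation stress genes HSPA1A was higher (0.89, SE 0.17) and FOS, an immediate-early transcription factor, lower (-1.17, SE 0.17), in both counts. Cell cycle genes had 0 of 16 passing, but 9 higher adjusted over the list alone, in classes from which the cycling cluster had been removed, so this does not compare division. MHC class I presentation (14 genes) and lysosomal genes (14 genes) had 0 passing, with 1 lower and 1 higher adjusted over the list alone, and quiescence and egress genes (11 genes) had 0 in both counts. Beyond the lists FAM129A, the apoptosis gene PMAIP1 and STAM were higher, and SCML4, ARMH1, the costimulatory receptor TMIGD2 and GPR171 were lower, SCML4 with 28.1 ± 14.4 against 132 ± 18.8 CPM. CCL4 was lower (-2.60, SE 0.42).

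By CPM without a floor, the direction held in 4 of 4 sources for each named gene that passed, except TNFRSF9, LGALS1, CISH and CCL4, in 3. For these and for IL21, AREG and HOPX at least 1 source had fewer than 3 counts in Treg-like cells, and a floor of 3 counts per sum turned the sign there or gave one to a gene without counts, so that source shows no direction. In edgeR's quasi-likelihood test with the source block and Benjamini-Hochberg adjustment, 118 of 8741 genes were higher in Treg-like cells and 95 lower, of which 4 were receptor segment genes. Adjusted p was 0.000341 for LAYN, 0.000552 for TIGIT, 0.0465 for CTLA4, 0.00482 for CCR8 and 0.00104 for TNFSF8. Camera called 9 of 14 lists, all up. They were interferon response (adjusted p = 0.000372), NF-kB targets (0.000372), checkpoint receptors (0.000646), MHC class II (0.000646), cell cycle (0.00103), chemokine receptors (0.00205), MHC class I (0.00307), lysosome (0.00622) and checkpoint ligands (0.0205). With an estimated correlation camera called 0, with adjusted p = 0.304, 0.284, 0.304, 0.304, 0.318, 0.318, 0.318, 0.304 and 0.304 in that order, and unadjusted p = 0.0203 for NF-kB targets and 0.0454 for checkpoint receptors, while fry called 1 list, NF-kB targets (adjusted p = 0.041). Cytokines had a median above 0 (0.23) with a mean (-0.31) and a test below it, the median of JAK-STAT targets (-0.01) was negative with a positive mean (0.32) and test, the mean of the cytotoxic list (-0.10) was negative with a positive median and test, and camera's sign was positive for the quiescence list with a negative median (-0.03) and mean (-0.23). The count of genes was 79 without source 2, 134 without source 3, whose 21 Treg-like cells were the fewest, 22 without the block, 88 with cells thinned to 1000 UMIs and 421 with coarser clusters, of which 103 were among the 213. With those coarser clusters IL21 and CCL4 had positive log2 differences that did not pass, 0.64 and 1.49. The coarser Treg-like cluster was a broader class, with FOXP3 in 39.0% of 1202 cells against 70.2% of 553 in the main clustering. FOXB1 was among its leading genes. In the main clustering FOXB1 led a separate CD4 T-like cluster that had IL21 among its leading genes and FOXP3 in 7.9% of cells.

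**Figure D2:**
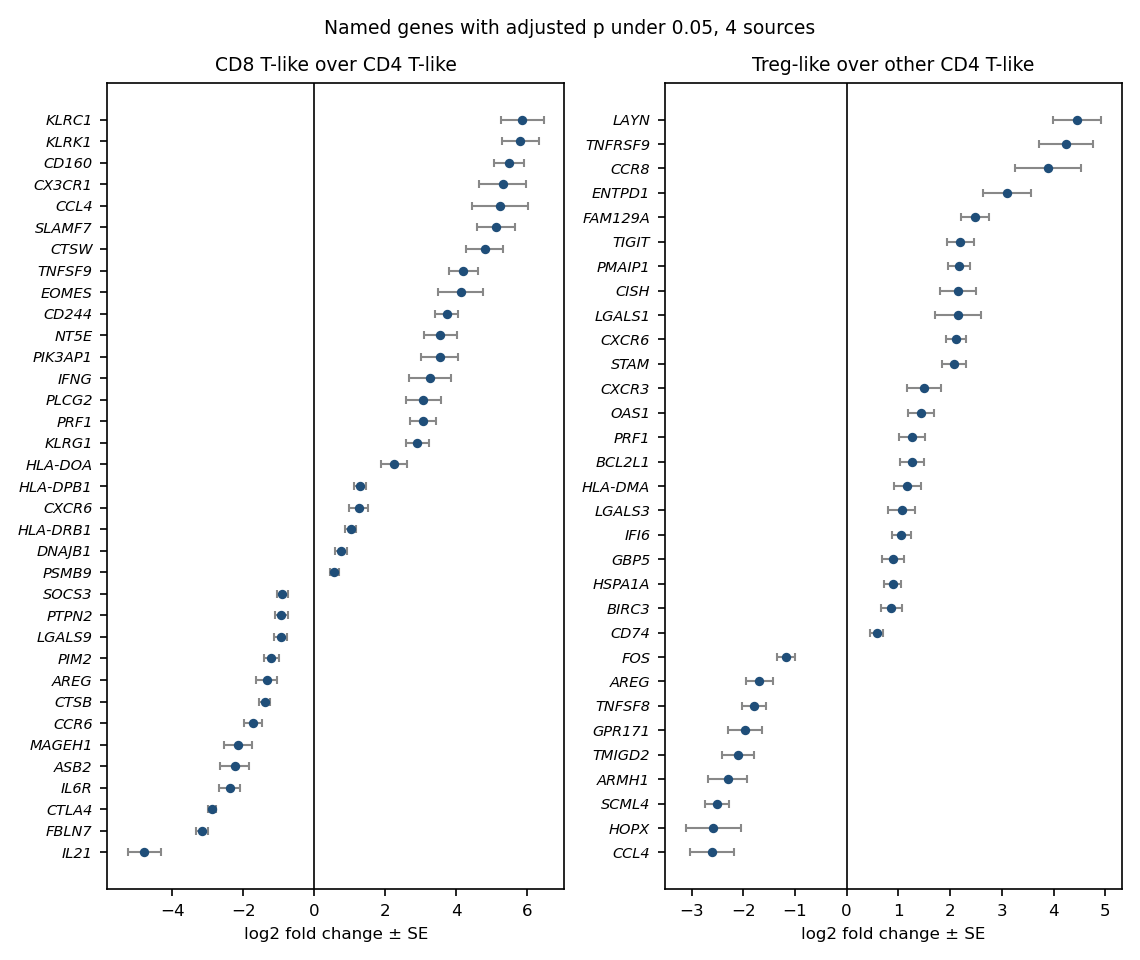
Log2 fold change (x axis, with the SE derived from the test as a bar) of the named genes (y axis) for CD8 T-like over CD4 T-like cells on the left and Treg-like over other CD4 T-like cells on the right, from 4 sources. KLRC1 is highest on the left at 5.85 and LAYN on the right at 4.45; genes with 3 counts or fewer in a class are not drawn.

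B-like cells differed from T-like cells most in MHC class II presentation and in B cell receptor signalling, where all tested list genes were higher. HLA-DRA, the alpha chain of the MHC class II molecule HLA-DR, stood at 6246 ± 803 CPM (SD, n = 4 sources) in B-like against 78.5 ± 17.2 in T-like cells. FCRLA, an intracellular Fc receptor-like protein of B cells, had 279 ± 72.3 against 0.351 ± 0.458 CPM, and BLNK, the adaptor that links the B cell receptor to its kinases, 236 ± 26.8 against 0.639 ± 0.755. IL6, a cytokine of inflammation, had 36.4 ± 17.3 CPM in B-like against 0.143 ± 0.156 in T-like cells. T-like cells were higher in LAG3 (120 ± 73.5 against 0.292 ± 0.354 CPM) and in IL32, a cytokine of activated T cells (2556 ± 112 against 16.4 ± 12.2 CPM).

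All 12 MHC class II genes were higher in B-like cells, with HLA-DOB at a log2 difference of 8.30 (SE 0.38) and HLA-DRA at 6.42 (SE 0.16). All 12 B cell receptor signalling genes were higher, FCRLA by 9.48 (SE 0.43), BLNK by 8.49 (SE 0.42) and the kinase BTK by 8.13 (SE 0.36). Of 15 checkpoint receptors 13 were lower and 2 higher. LAG3 (-7.27, SE 0.52), CTLA4 (-6.54, SE 0.48) and PDCD1 (-5.78) were lower, and BTLA (1.24) and ENTPD1 (2.71) higher, and LAYN, with 0 counts in B-like cells, was at least 12.5-fold lower against a floor of 3 counts over the group. Checkpoint ligands and suppressive factors had 8 of 12 higher and 2 lower. Among them CD86, a ligand of CD28 and CTLA4 (6.50, SE 0.35), and ICOSLG, the ligand of ICOS (4.17, SE 0.39), were higher, and CD274, the gene of PD-L1, lower, at 0.365 against 3.29 CPM. SIRPA was 99.9 times higher by its 60 counts against 2 (95% counting interval 26.5 to 844). These 4 lists had the same counts adjusted over the list alone. Chemokine receptors had 7 of 11 lower and 2 higher in both counts, with CXCR6 (-7.41, SE 0.37) and CCR4, the receptor of CCL17 and CCL22 (-7.34, SE 0.30), lower and CCR6 (2.54) higher, while CCR8, at 0 counts in B-like cells, was at least 17.0-fold lower. Of 12 cytotoxic effectors 10 were lower and 1 was higher in both counts, with PRF1 (-6.58, SE 0.29) and the granzyme GZMM (-6.57, SE 0.35) as examples. Cytokines split into 5 higher and 9 lower of 20, or 6 and 11 adjusted over the list alone. IL6 (8.90, SE 0.40) and TNFSF13, the plasma cell survival factor APRIL (7.18, SE 0.37), were higher, and IL10, with 2 counts in B-like cells, was 95.6 times lower (95% counting interval 26.4 to 791). Interferon response genes had 14 of 27 higher and 2 lower, or 16 and 3 adjusted over the list alone, with IFIT2 (2.90, SE 0.37), IFI44L (2.88, SE 0.32) and IFIT3 (2.48, SE 0.26) higher. The summed level of the list was nonetheless 3269 ± 2048 CPM in B-like against 4276 ± 388 in T-like cells, and only source 1, at 6275 CPM, had B-like cells above the T-like mean. NF-kB targets split evenly, 7 higher and 7 lower of 19 in both counts, with CD83, an activation marker of B and dendritic cells (6.23, SE 0.40), higher and the adaptor TRAF1 (-3.80, SE 0.22) and IER3 lower. JAK-STAT targets had 4 higher and 8 lower of 16, or 5 and 10 adjusted over the list alone, PIM1 (-3.01, SE 0.28) and SOCS3 (-2.46, SE 0.34) being lower, and SOCS2 was 26.9 times lower by its 2 counts (7.33 to 224). Cell cycle genes had 3 higher and 9 lower of 21, or 4 and 9 adjusted over the list alone, with TYMS (-2.76, SE 0.37), CENPF and TOP2A lower, but the cycling cluster of mostly CD3D-positive cells had been left out, so the split reflects that filter as well. Quiescence and egress genes had 4 of 11 higher and 3 lower, or 5 and 3 adjusted over the list alone, BACH2, a repressor of plasma cell fate (2.85, SE 0.38), against ITGA6 (-4.64, SE 0.27) and SATB1. MHC class I presentation split 4 and 4 of 14 in both counts, with the peptide transporter TAP2 higher (0.87, SE 0.17) and ERAP1 and NLRC5 lower. Lysosomal genes had 6 higher and 4 lower of 14, or 7 and 5 adjusted over the list alone, CTSZ (2.60, SE 0.16) and GRN (2.58, SE 0.19) against CTSL (-4.21, SE 0.43). Of 7 chemokines CXCL16 was higher (2.19, SE 0.49) and CCL4 (-3.06, SE 0.54) and CCL20 lower, in both counts, CCL20 at least 16.5-fold by its 0 counts in B-like cells. Of 17 dissociation stress genes 0 were higher and 5 lower in both counts, with HSPA1A (-1.83, SE 0.22), HSPB1 and DNAJB1 as examples. Among tested genes with a mean of at least 50 CPM in the higher class, receptor segment genes left aside, CD180, GAPT and the transcription factor HHEX were also among the 5 with the highest fold in B-like cells, and TIAM1 among the 5 with the lowest.

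By CPM without a floor, named genes that passed had the same direction in 4 of 4 sources. For TYMS, SOCS2, TOP2A, CENPF, IER3, CCR8, LAYN and CCL20, B-like cells of source 3 had fewer than 3 counts and a floor of 3 counts per sum turned the sign, so source 3 shows no direction for them, nor does source 2 for CCL20. The test, edgeR's quasi-likelihood with the source block and Benjamini-Hochberg adjustment, called 1881 of 11436 genes higher in B-like and 2071 higher in T-like cells, 231 of them receptor segment genes. Adjusted p was 3.17e-07 for HLA-DRA, 6.29e-07 for FCRLA, 6.25e-07 for IL6 and 7.17e-06 for LAG3. Camera called 7 of 16 lists, up for MHC class II (adjusted p = 5.40e-13), B cell receptor signalling (2.27e-12), interferon response (0.0026) and checkpoint ligands (0.00452), and down for checkpoint receptors (0.000138), cytotoxic effectors (0.00452) and chemokine receptors (0.00706). With an estimated correlation camera called 0, with adjusted p = 0.384, 0.0976, 0.468, 0.384, 0.457, 0.468 and 0.468 in that order and an unadjusted p of 0.0061 for B cell receptor signalling, while fry called 11. Without the block 2254 genes passed. Source 3 entered with only 90 B-like cells. B-like cells came mostly from a cluster with FCER2 among its leading genes in sources 1 and 2 (1466 of 1497 and 719 of 775 cells) and from a CD83-led cluster in sources 3 and 6 (90 of 90 cells and 2134 of 2199 in Run1).

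Myeloid-like cells stood apart from T-like and B-like lymphocytes by chemokines, lysosomal genes, checkpoint ligands and single cytokines such as IL1B, while the cytokine list split. IL1B, a cytokine released by inflammasomes, had 412 ± 274 CPM (SD, n = 4 sources) in myeloid-like against 0.328 ± 0.20 in lymphocyte sums. CCL18, a chemokine of alternatively activated macrophages, had 1678 ± 1837 against 2.87 ± 2.96 CPM, and IDO1, the tryptophan-degrading enzyme that restrains T cells, 304 ± 320 against 0.589 ± 0.681 CPM. CD274, the gene of PD-L1, had 25.5 ± 11.9 against 2.61 ± 0.561 CPM, and PDCD1LG2, the gene of PD-L2, 22.2 ± 11.6 against 1.45 ± 1.22. CD28, the costimulatory receptor of T cells, had 3.68 ± 4.54 CPM in myeloid-like against 120 ± 44.5 in lymphocytes.

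Chemokines were higher in 13 of 14 tested genes and lower in 0, among them the neutrophil attractant CXCL8 (log2 difference 10.48, SE 0.70), CXCL2 (9.95, SE 0.91), CCL18 (9.04, SE 0.37) and CXCL9 (8.73, SE 0.59), an interferon-induced ligand of CXCR3. CXCL8 (71.8 ± 130 CPM) and CXCL2 (105 ± 206 CPM) came mostly from source 6, with log2 ratios of 10.81 and 10.34 there, against 2.42 to 4.31 and 2.42 to 4.03 in the other sources, which lay at or near a floor of 3 counts per sum. Checkpoint ligands and suppressive factors had 12 of 17 higher and 1 lower, with IDO1, NECTIN2, a ligand of TIGIT (7.79, SE 0.26), SIRPA, the receptor of the CD47 signal (6.41, SE 0.46), PDCD1LG2 (4.48, SE 0.46) and CD274 (3.22, SE 0.43) higher. Lysosomal genes had 11 of 14 higher and 0 lower, such as CTSL (4.44, SE 0.86), CTSZ (4.16, SE 0.21) and the growth factor precursor GRN (4.14, SE 0.23). MHC class II genes had 11 of 12 higher and 0 lower, HLA-DRA by 2.53 (SE 0.31). The lymphocyte sums mix T-like and B-like cells, and the summed list was at 49203 ± 7794 CPM in myeloid-like, 47658 ± 3496 in B-like and 1868 ± 682 in T-like cells, so the excess came from the T-like part and depends on the B-like share. The lists of chemokines, checkpoint ligands, lysosome and MHC class II had the same counts adjusted over the list alone. NF-kB targets had 11 of 20 higher and 0 lower, or 12 and 0 adjusted over the list alone, with TNFAIP2 (9.37, SE 0.29), IER3 (5.34, SE 0.38) and the mitochondrial dismutase SOD2 (3.88, SE 0.22). Cell cycle genes had 14 of 25 higher and 2 lower, or 15 and 2 adjusted over the list alone, with UBE2C (4.41, SE 0.59), CCNB2 (3.66, SE 0.87) and AURKB (3.53, SE 0.62), which drive mitosis. UBE2C had 110 counts over all myeloid-like cells. The cycling cluster had been left out of the lymphocytes, while any cycling cells within the myeloid-like clusters stayed in, so these counts do not show that myeloid-like cells divided more. Dissociation stress genes had 11 of 17 higher and 2 lower, or 12 and 2 adjusted over the list alone, among them ATF3 (4.24, SE 0.26), FOS (2.33, SE 0.66) and HSPA1A (2.28, SE 0.29). Quiescence and egress genes had 10 of 11 lower and 0 higher in both counts, with S1PR1, the receptor that leads lymphocytes out of nodes (-3.74, SE 0.27), ITGA6 (-3.22, SE 0.42) and BACH2 (-2.90, SE 0.40). Cytotoxic effectors had 8 of 11 lower and 2 higher in both counts, and with 0 counts in myeloid-like cells EOMES was at least 14.6-fold and KLRK1 at least 7.72-fold lower, while TBX21 was 27.7 times lower by its 1 count (4.95 to 1100). Checkpoint receptors had 4 higher and 7 lower of 13, or 4 and 8 adjusted over the list alone, with HAVCR2, the gene of TIM-3 (2.18, SE 0.31), and VSIR (1.53, SE 0.29) higher and CD96 (-4.61, SE 0.41), CTLA4 (-4.54, SE 0.47) and TIGIT (-4.13, SE 0.37) lower. Cytokines split into 10 higher and 10 lower of 22 in both counts, IL1B (10.52, SE 0.31), VEGFA, an angiogenic factor (8.19, SE 0.79), and IL18 (7.20, SE 0.47) being higher. VEGFA had a log2 ratio of 8.90 in source 6 and 4.025 to 5.475 in the other sources, source 1 lying at the floor of 3 counts per sum. Chemokine receptors had 4 higher and 5 lower of 9 in both counts, CCR1 (5.28, SE 0.35) against CXCR6 (-5.32, SE 0.54) and CCR4 (-4.46, SE 0.45). JAK-STAT targets had 5 higher and 2 lower of 16, or 5 and 4 adjusted over the list alone, JAK2 (1.59, SE 0.18) against PIM2 (-2.96, SE 0.24) and BCL2 (-2.47, SE 0.30). B cell receptor signalling had 3 higher and 5 lower of 12 in both counts, the kinase LYN (2.60, SE 0.23) against FCRLA (-5.13, SE 0.42) and BLK (-4.62, SE 0.31). Interferon response genes had 4 higher and 3 lower of 27 in both counts, WARS (2.58, SE 0.36) against IFITM1 (-3.50, SE 0.59) and ISG20 (-2.53, SE 0.35), and MHC class I presentation 1 higher and 3 lower of 14 in both counts, TAP2 (1.52, SE 0.21) against HLA-E (-1.05, SE 0.21) and NLRC5 (-1.44, SE 0.24). Outside the lists, CD33, a sialic acid-binding receptor, and the metalloproteinase MMP19 had 2 counts each in lymphocytes, ratios of 1920 (527 to 16000) and 5340 (1470 to 44200). MMP19 (92.7 ± 148 CPM) came mostly from source 6, and without it the log2 difference fell from 12.16 to 7.23. CD28 (-4.78, SE 0.46), CD27, THEMIS and TC2N were lower.

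By CPM without a floor, the direction was shared by 4 of 4 sources for each named gene that passed, except FOS, in 3. For KLRK1 and TBX21 a floor of 3 counts per sum turned the sign in source 3, which shows no direction for them. In edgeR's quasi-likelihood test with the source block and Benjamini-Hochberg adjustment, 2152 of 10824 genes were higher in myeloid-like cells and 2358 lower, with 176 receptor segment genes among them. Adjusted p was 1.09e-07 for IL1B and IDO1, 2.77e-07 for CCL18, 0.000317 for CD274 and 4.08e-05 for CD28. Camera called 9 of 16 lists, up for lysosome (adjusted p = 9.22e-07), NF-kB targets (4.86e-06), chemokines (5.96e-06), MHC class II (1.36e-05), checkpoint ligands (5.26e-05), cell cycle (8.14e-05) and dissociation stress (0.003), and down for quiescence and egress (0.000848) and cytotoxic effectors (0.0153). With an estimated correlation camera called 0, with adjusted p = 0.344, 0.344, 0.196, 0.533, 0.196, 0.646, 0.298, 0.267 and 0.533 in that order and unadjusted p = 0.0188 for checkpoint ligands and 0.0245 for chemokines, while fry called 7. JAK-STAT targets had a positive median (0.29) and camera sign with a mean (-0.01) below 0, and B cell receptor signalling a positive median (0.07) and camera sign with a negative mean (-0.55). With cells thinned to 1000 UMIs the number of genes differing, myeloid-like versus lymphocytes, was 2172, of which 2054 were among the 4510. A PLA2G2D-led cluster of low depth held 192 of 269 myeloid-like cells in source 1, and an FCN1-led cluster 173 of 227 in source 2.

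**Figure D3:**
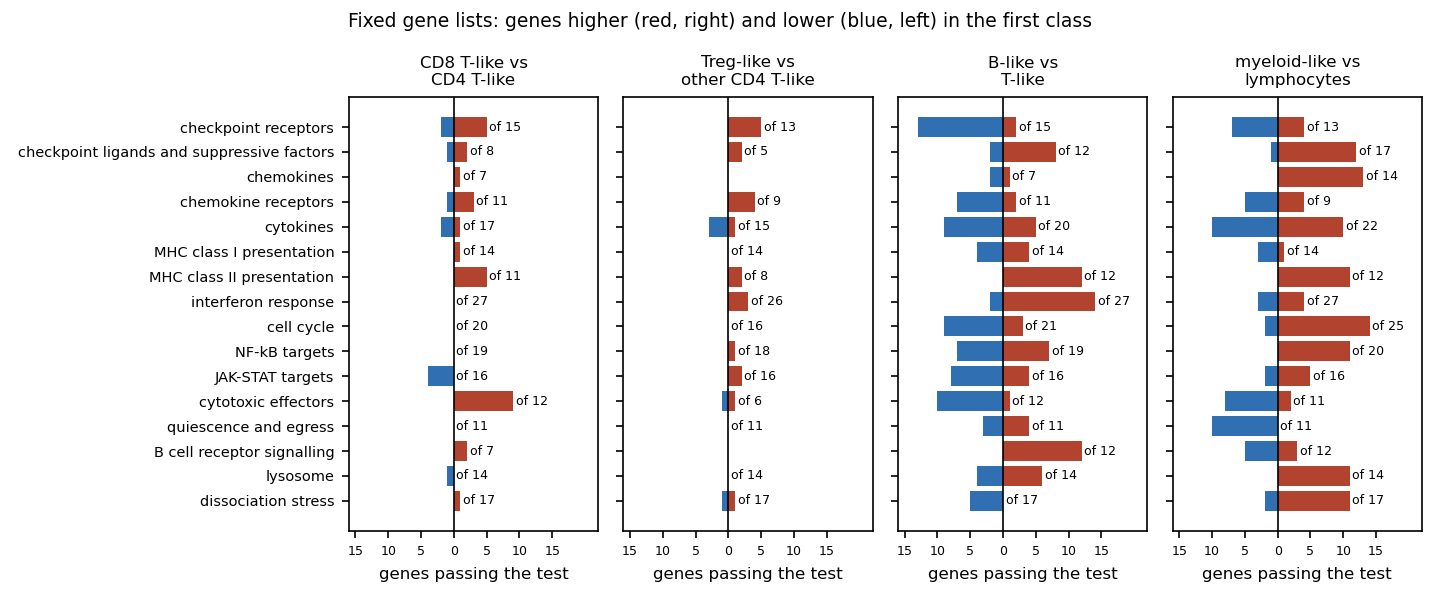
Number of genes of each fixed list (y axis) that passed the test as higher (red bars, right) or lower (blue bars, left) in the first class of each of 4 comparisons (panels), with the number tested written at the bar. All 12 MHC class II and all 12 B cell receptor signalling genes were higher in B-like cells, and 13 of 14 chemokines in myeloid-like cells.

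Mean levels of the checkpoint genes did not share the same order of classes, though not each difference was tested or passed. PDCD1 passed neither for CD8 T-like against CD4 T-like nor for Treg-like against other CD4 T-like cells. PDCD1 had 58.7 ± 27.6 CPM (SD, n = 4 sources) in CD4 T-like cells without Treg-like cells, 61.5 ± 46.9 in CD8 T-like and 27.3 ± 7.13 in Treg-like cells. CTLA4 was 575 ± 279 CPM in Treg-like and 257 ± 161 in CD4 T-like cells. TIM-3, encoded by HAVCR2, stood at 37.2 ± 31.3 CPM in CD8 T-like, 62.7 ± 34.9 in NK-like and 38.3 ± 6.04 in myeloid-like cells, against 6.36 ± 2.03 in CD4 T-like cells without Treg-like cells. The difference of HAVCR2 between CD8 T-like and CD4 T-like cells, here with Treg-like cells included (7.35 ± 2.37 CPM), passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0338, log2 difference 1.85, 4 of 4 sources), while that of TIGIT did not (0.451, log2 difference 0.51, 3 of 4 sources). The class that included NK-like cells was not tested. CD40LG, the helper signal for B cells, had 128 ± 24.4 CPM in CD4 T-like cells, but it served as a marker of that class. Gene positions on GRCh38 from GENCODE 29 are chromosome 2, 203867771 to 203873965 for CTLA4 (ENSG00000163599), chromosome 3, 114276913 to 114310288 for TIGIT (ENSG00000181847), chromosome 12, 6772512 to 6778455 for LAG3 (ENSG00000089692), chromosome 11, 111540280 to 111561745 for LAYN (ENSG00000204381), chromosome 8, 39902275 to 39928444 for IDO1 (ENSG00000131203) and chromosome 6, 32439842 to 32445046 for HLA-DRA (ENSG00000204287).

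**Figure D4:**
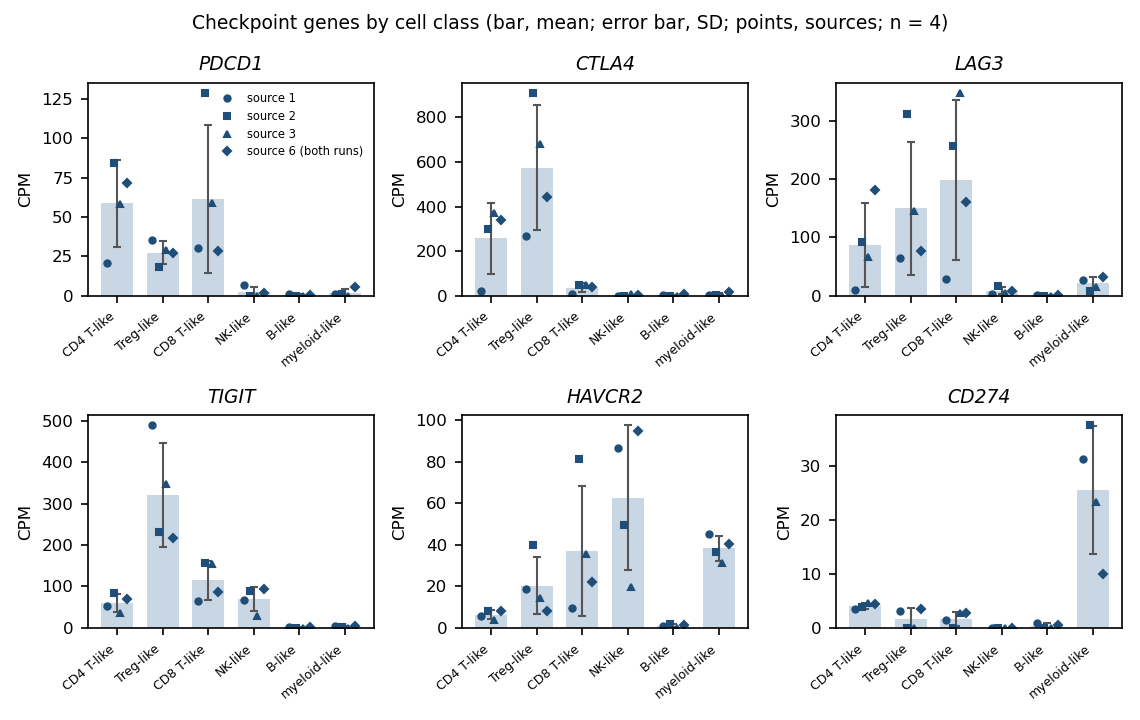
CPM (y axes) of 6 checkpoint genes in 6 cell classes (x axes), with the mean of 4 sources as a bar, the SD as an error bar and each source as a point. CTLA4 was highest in Treg-like cells at 575 CPM and CD274 in myeloid-like cells at 25.5 CPM.

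Between the sources, summed levels of the fixed lists differed by up to several fold in the same class, with no test and with source 6 summed over its 2 libraries. The checkpoint receptor list summed to 531 CPM in T-like cells of source 1 (95% Poisson interval 518 to 544), 1088 in source 2 (1054 to 1122), 1022 in source 3 (985 to 1060) and 882 in source 6 (872 to 892). The value of source 6 pools 1592 in Run1 (1562 to 1623) and 713 in Run2 (703 to 723), a gap as wide as that between the sources. The T-like sums draw on different clusters. In source 1 a cluster with CCR7 and ITGA6 among its leading genes held 1759 of 1904 CD4 T-like cells. It held 320 cells in source 2, 5 in source 3, 40 in Run1 and 20 in Run2. The interferon response list in B-like cells summed to 6275 CPM in source 1 (6217 to 6335), against 1703 in source 2 (1648 to 1760), 2375 in source 3 (2184 to 2577) and 2722 in source 6 (2683 to 2762). Myeloid-like cells showed the same order at the top, with 6240 CPM in source 1 (6101 to 6383) and 1110 in source 2 (1049 to 1174). The dissociation stress list moved with the source too, from 2631 CPM in T-like cells of source 1 (2603 to 2659) to 10591 in source 6 (10556 to 10625). The intervals cover counting error only.

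The runs of source 6 were set side by side to show how much libraries given the same source number differ, with 1 library each and no test. B-like cells made up 36.2% of cells in Run1 (95% Clopper-Pearson interval 34.96 to 37.39) and 7.02% in Run2 (6.46 to 7.61), and CD8 T-like cells 5.72% (5.15 to 6.34) and 21.4% (20.5 to 22.3). CD4 T-like cells with Treg-like cells were at 43.5% (42.3 to 44.8) in Run1 and 43.8% (42.7 to 44.9) in Run2. These shares leave out a cluster unnamed for its low depth, with CD3E in 67.4%, CD4 in 16.6% and CD8A in 0.5% of cells. It held 12 cells in Run1 and 782 in Run2, so the near-equal shares depend on that filter. By the fixed rule of size, at least 2-fold with at least 50 CPM in the higher library, 288 of 2869 genes differed, 161 higher in Run1 and 127 in Run2. Run1 was higher in TCL1A, a gene of naive and germinal centre B cells (361 against 39.6 CPM), and in CCL17, a chemokine ligand of CCR4 (51.0 against 2.87 CPM). Run2 was higher in VWF, an endothelial gene (65.3 against 1.94 CPM) and the lymphatic chemokine CCL21 (57.8 against 0.08 CPM, from 1 count in Run1). Among T-like cells alone 148 of 2817 genes met the rule, 106 of them higher in Run1. Among those were CXCL13, which draws B cells to follicles, at 6260 CPM (6200 to 6321) against 2037 (2020 to 2054), and TOX2 at 267 against 60.7. LAG3 had 369 CPM (354 to 384) against 119 (115 to 123), and TIGIT 183 (173 to 193) against 51.3 (48.6 to 54.0). Genes not particular to T cells differed by larger folds, such as COTL1 (1442 against 203 CPM) and RAC1 (208 against 29.6). They also differed in the whole libraries, COTL1 at 1082 against 194 CPM and RAC1 at 228 against 42.7. The genes named here thus do not describe the whole set. S1PR1, which guides lymphocytes out of nodes, was higher in Run2, at 76.4 against 25.6 CPM. A cluster with TOX2 among its leading genes held 1998 of 3387 T-like cells in Run1 and 64 of 5125 in Run2, so values within the class came mostly from different clusters. Median UMIs per kept cell were 1735 in Run1 and 4530 in Run2, and with each cell thinned to 1000 UMIs 275 genes met the rule, 231 of them among the 288.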

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

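The tests of explanations for the neuronal cluster, the marker-positive large cells and the runs, and the counts over other splits of the samples, were chosen after the results were seen. A value of 1 source was singled out where it lay far from those of the other 3 by Dixon's ratio. Of 245 groups of 4 values 15 held such a value, where chance gives about 12.2, so the number by itself is near chance.

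In CD8 T-like over CD4 T-like cells, PRF1 had a log2 ratio of 1.42 in source 1 against 3.48 to 3.59 in the others, and MAGEH1 had -0.42 in source 1 against -3.09 to -2.78. The mean over checkpoint receptors was 1.31 in source 2 and 0.39 to 0.45 in the others. In Treg-like over other CD4 T-like cells FAM129A had 1.24 in source 3 and 2.70 to 2.82 in the others.

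In B-like over T-like cells TYMS had 3.13 in source 3 against -2.93 to -2.48, SOCS2 had 3.55 against -3.29 to -2.31, and the cell cycle mean 1.63 against -1.07 to -0.70. Source 3 had 90 B-like cells, and sums with fewer than 3 counts were set to a floor of 3 counts. That floor sets the values of TYMS and SOCS2 in source 3 and enters the cell cycle mean, so these show no direction in source 3. DNAJB1 had -1.71 in source 3 against -0.96 to -0.91. FCRLA had 10.78 in source 6 against 8.09 to 8.47, and the dissociation stress mean was -0.15 in source 6 against -0.67 to -0.60.

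In myeloid-like cells over lymphocytes CCNB2 had 0.83 in source 2 against 3.95 to 4.57, and the cytokine mean 0.53 in source 2 against 0.95 to 0.96. IER3 had 6.42 in source 6 against 4.54 to 4.79, and MMP19 had 12.05 in source 6 against 4.03 to 5.31. For MMP19 the floor of 3 counts sets the lymphocyte level in all 4 sources and both classes in source 1, so its ratios outside source 6 are not measured sizes. BLK had -0.75 in source 3 against -4.88 to -4.34, with the same floor of 3 counts.

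Cells outside all named classes held neuronal genes, a signal in data that no comparison used. A cluster of 76 cells in source 1 and 55 in source 2 was led by MEG3, GRIA2, SNAP25 and SYT1. All 55 barcodes of the cluster in source 2 were among the 76 of source 1, where the rate of the other library pairs gives 0.00595, which argues against separate neurons caught in each biopsy. The leading genes were at least 1960 times higher at equal depth in the cluster than in the other barcodes. They were picked by their fold in the cluster, so this ratio cannot test free RNA. A set of 9 neuron genes, none among the leading genes, had 3978 against 1.11 CPM in source 1 and 3946 against 1.49 in source 2. This argues against free RNA spread over all droplets. A first version of the test found 8.95% and 10.0% of the UMIs of the leading genes outside the cluster's barcodes. Molecules carried under the same barcodes into both libraries, 55 shared, are what stays open, as a candidate explanation, and UMIs per shared barcode correlated between the libraries (r = 0.961). No biological explanation was tested.

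Large cycling cells of Run1 carried Reed-Sternberg markers, also outside all comparisons, and of those with at least 10000 UMIs 13 of 24 had at least 3 of the markers, against 5 of 24, 2 of 38 and 0 of 8 in sources 1, 2 and 3 and 2 of 30 in Run2. Over all kept cells 33 in Run1 had at least 3, against 28, 17 and 2 in the sources and 49 in Run2, so Run1 stood out only among the large cycling cells, where the list at equal depth was 6.15 times the highest of the other libraries, which argues against depth. T and B marker lists reached at most 0.90% of their own class, which argues against doublets, though the CD4 T list reached 13.0% with CCR7 giving 57 of 66 counts, and the CD8 T list 38.6% with CCL5 giving 205 of 207. The monocyte/macrophage list reached 0.115% of the myeloid-like level, which argues against macrophages. The dendritic list reached 29.3%, with BATF3 giving 105 of 106 counts. In it 8 of 9 genes lay under 20% of the myeloid-like level, which argues against dendritic cells. TFPI2 and TUBB2B, among the genes most raised in these cells, were also leading genes of the dendritic-like cluster, which weakens that point. The Reed-Sternberg list itself was at 1700 CPM in the marker-positive cells and at 1183 CPM in the myeloid-like cells of Run1. By itself the summed list does not part these cells from myeloid-like cells. In the latter most of that level came from CCL17, seen in 38 of 6080 kept cells of Run1. The rest of the list was higher in the marker-positive cells, which were chosen by the list. That these are malignant Reed-Sternberg cells is a hypothesis found and tested on the same data, and no group of the design bears on it.

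Run1 and Run2 of source 6 differed in 288 genes by size. With all cells thinned to 1000 UMIs, 231 of these stayed in the same direction. The levels were already scaled to equal totals, and random thinning keeps the expected proportions of genes within a cell. The thinning thus cannot decide whether differences tied to depth contributed. In T-like cells, equal weights for the 3 clusters with at least 100 cells in both runs kept 87 of 148 genes in the same direction. A first version with 9 clusters kept 82. For the clusters covered, this argues against sampled clusters as the whole cause. The 3 clusters held only 312, 377 and 126 of 3387 T-like cells in Run1 and 651, 630 and 124 of 5125 in Run2. The most uneven cluster, with 1998 and 64 cells, entered only the first version, so how much uneven clusters contribute stays open. The summed stress list was 1.49 times higher in Run1, and stress during handling cannot be told apart from other differences, since the value lies just under the bound set for excluding it and each run is 1 library, with no spread between libraries. What a run was is not in the labels, and no biological explanation was tested.

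Other splits of the 8 sums were tested for the 4 comparisons. Only 8 splits part each pair of classes within a source, too few for a share under 0.05. With the block the real one gave 379, 213, 3952 and 4510 genes for CD8 T-like, Treg-like, B-like and myeloid-like cells, and the highest other gave 0 each. Over all 35 splits without the block, most of which mix sources with classes, the real one gave 36 genes (highest other 28), 22 (8), 2254 (1) and 3238 (0). The classes were formed from the expression of the same cells, so a difference between them is partly built in, though the clustering genes and markers were left out of the tests.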

How the results depend on the processing

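Robust dispersion estimates and the settings with only the GZMK-led CD8 cluster, without the FOXB1-led cluster and without the PLA2G2D-led cluster were chosen after seeing the data. Of the named genes, Treg-like over other CD4 T-like kept direction and side of the threshold in 480 gene and setting pairs and lost the call in 121, B-like in 920 and 16 and myeloid-like in 991 and 11, while CD8 T-like over CD4 T-like lost it in 106. The log2 difference turned positive, without passing, for IL21 (0.64, adjusted p = 0.252) and CCL4 (1.49, adjusted p = 0.532) in Treg-like cells at Leiden resolution 0.6, and in no other named gene and setting.

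The number of genes differing, CD8 T-like versus CD4 T-like, was 1209 without the low-count filter, and that of genes differing, Treg-like versus other CD4 T-like, was 550. Without the block 36 and 22 passed in these, and for genes differing, B-like versus T-like, 2254. With glmTreat 85, 22 and 1719 passed, and for genes differing, myeloid-like versus lymphocytes, 1698. The range over the left-out sources was 79 to 964 for CD8 T-like, 79 to 227 for Treg-like, 2737 to 3744 for B-like and 3091 to 4418 for myeloid-like cells. The GZMK-led cluster alone gave 918. For Treg-like cells, Leiden resolution 0.6 gave 421, of which 103 were among the 213, and at least 50 cells per source, which leaves out source 3, gave 134. Thinning to 1000 UMIs gave 88 for Treg-like and 2172 for myeloid-like cells. The causes were not tested, apart from fewer samples or counts where a setting removes them. Robust estimates gave 401, 268, 4023 and 4527 genes, of which 339, 197, 3891 and 4449 were among the first counts.

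Camera with an estimated correlation called 0 lists in each of the 4 comparisons, against 4, 9, 7 and 9 with the preset correlation, and fry called 0, 1, 11 and 7. Mean shares stayed within 1 SD in 89 of 90 cases, and the Treg-like share was 5.62% at Leiden resolution 0.6. The 288 genes of Run1 against Run2 became 528 at 20 CPM, 115 at an absolute log2 ratio of 2 and 148 in T-like cells only. Depth limits the small classes, with 21 Treg-like and 39 myeloid-like cells in source 3.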

Other observations

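The cells with Reed-Sternberg markers in Run1 carried cytokines and chemokines, some of which few other cells held. The genes named here were chosen after their values were seen, and all values come from 13 cells of 1 library with no test. CCL22, a ligand of CCR4, had 646 CPM and was seen in 13 of 13 cells, against 1.52 CPM in the other cells of Run1. IL9, a cytokine of T helper cells, had 682 CPM with 1 count elsewhere, and IL13 had 94.4 CPM. BATF3, a transcription factor, had 320 against 3.27 CPM, GTSF1 500 against 8.30 CPM and DHRS2 801 CPM. CCL17 had 372 CPM, below the 747 CPM of myeloid-like cells in Run1, and TNFRSF8, the gene of CD30, 36.6 CPM against 5.21 in T-like cells. CCL17, IL13 and TNFRSF8 were among the markers by which the cells were chosen. Their median depth was 26612 UMIs, from 12622 to 37472.

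CCR4, the receptor of CCL17 and CCL22, was at 95.5 ± 71.1 CPM (SD, n = 4 sources) in CD4 T-like, 114 ± 85.2 in Treg-like and 14.1 ± 6.62 in CD8 T-like cells. CCL17 was at 309 ± 451 CPM in myeloid-like cells. Few cells carried it, and 1 cell held 93.5% of the 1083 counts of source 2, 85.7% of the 35 of source 1 and 22.1% of the 655 of Run1. CXCL13 was at 3037 ± 2030 CPM in CD4 T-like cells.

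Haemoglobin RNA differed between libraries. HBB had 0 counts in Run1, a level under 0.224 CPM, against 7618 CPM in Run2 and 211, 2289 and 153 CPM in sources 1, 2 and 3.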
